A study of Anguilla anguilla with 12 samples.

How the data were processed

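Small RNA libraries had been made from the livers of 12 European eels (Anguilla anguilla), 6 from Arcachon Bay and 6 from the Gironde Estuary. Per the labels, RNA was isolated with a kit for microRNA and the libraries were made with a small RNA kit for Illumina sequencing. The submitters' processing notes name bcl2fastq 2.17.1.14, a program that turns base calls into reads per library. MicroRNAs (miRNAs) are short RNAs cut from hairpin precursors. The arm of the hairpin that usually has more reads is called the mature arm, the other the star arm, and the part between them the loop.

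The values analysed were 1 list of 820 precursors predicted with miRDeep2, per the file headers. This program looks for hairpins whose read pattern resembles cutting by the enzyme Dicer. The authors deposited for each precursor a mature read count, a star read count, a loop read count and a total read count. These are whole numbers with no normalization, and the total equalled the sum of the other 3 parts in 820 of 820 entries. The authors also deposited the miRDeep2 score of each precursor, a log-odds score that has no upper limit and ran from 0 to 7104894.2 in this list. No column names a sample, so each count is a single value, taken here as pooled over libraries. Which of the 12 libraries entered the prediction is not given in the sources used here. The depth of single libraries is therefore unknown, and no mean, standard deviation or test between eels was computed. Where the interval of a share is given, it is an exact binomial (Clopper-Pearson) 95% interval, and it covers counting error only. It covers neither the spread between eels nor copies made in amplification, since no molecular identifier is recorded. The aligner, the mismatches allowed, the trimming and the miRDeep2 version are not given in the sources used here.

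The precursors lie on numbered scaffolds of a whole-genome shotgun assembly of the European eel, named in the coordinates of the list. Scaffold numbers are given here as in the list, and the name of the build is not given in the sources used here. The end minus the start equalled the precursor length in 820 of 820 entries, so the listed start counts from 0 and 1 was added to it here. No annotation of that assembly was used here, so the genes around a precursor are not stated. A separate table of eel genes from another assembly was not used here.

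Names come from 1 column of the list, which gives an example of a zebrafish miRNA with the same seed (bases 2 to 8 of the mature sequence, counted from its 5′ end). A name such as let-7j therefore stands for every miRNA with that seed and does not separate members of a family. Entries with such an example are called seed-matched and the others unmatched. The columns for an Rfam alert, a significant randfold p-value, a miRBase name and a true-positive probability were positive or filled in 0 entries. They could separate nothing, and the planned tests on them were left out.

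Of 104 mature sequences listed at 2 or more entries, 98 had mature read counts within 10% of each other at all of their entries, and 58 had equal counts. Reads of such copies appear to be counted at each copy. Entries with an identical mature sequence were therefore counted once, at their highest mature read count, wherever reads were shared out. Mature sequences that differ by a base or in length stayed separate although reads could be counted at both. The arm was read from the position of the mature sequence in the precursor, for precursors with at least 10 mature plus star reads. Clusters were precursors on 1 scaffold and strand with neighbouring starts within 10 kb, after overlapping predictions were merged to the one with more reads. Yes-or-no properties of seed-matched and unmatched mature sequences were compared with two-sided Fisher's exact tests, adjusted after Benjamini and Hochberg over 7 properties, of which only the star reads had been planned before the data were examined. The other 6 properties were chosen after the values had been seen. Sequences are not independent replicates of eels, and related sequences are not independent of each other.

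The planned comparison of the 2 sites, a count test of 6 against 6 livers, and its miRNA lists between sites needed counts per eel and were not analysed here. The 22 lists of miRNA families were fixed beforehand and were used instead to describe how the pooled reads are divided. The rule for named miRNAs took the 20 seed-matched mature sequences with the most reads, the 5 unmatched ones with the highest score and the 5 with the most reads, and the 5 precursors with the highest star share among those with at least 1000 mature plus star reads. It also took the 3 largest clusters, with ties, and up to 4 members of each list. Alternatives were scores of at least 1, 4 and 10, minimum reads, other ways to count copies, and cluster distances of 3 and 50 kb. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used. The functions for copies, arms, overlaps and clusters were tested on simulated data of 563 precursors and returned 5 of 5 known quantities.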

Results

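Small RNAs were sequenced from the livers of yellow eels, the growth stage of the European eel, taken at a site the study describes as pristine and at one it describes as polluted. There were 6 animals from Arcachon Bay and 6 from the Gironde Estuary. The study's question was which liver miRNAs differ between the sites. The values analysed here are read counts of predicted miRNA precursors with no division by animal, so they describe liver miRNAs of the libraries as a whole. Which libraries entered the list is not given in the sources used here. No difference between the sites is reported. The list held 820 precursors on 648 scaffolds, with 388295038 mature reads, 2342616 star reads and 2152 loop reads summed over entries. The mature reads of single precursors ran from 2 to 176573973. Precursors were 38 to 100 nt long with a median of 60 nt, and 22 nt was the most frequent mature length, found in 320 of 676 distinct mature sequences.

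The pooled liver libraries were dominated by miR-122, the liver-specific miRNA of vertebrates. Its mature sequence uggagugugacaaugguguuu, from a hairpin on scaffold 297 (231110 to 231167, minus strand), held 176573973 mature reads. That was 64.8% of the 272589277 mature reads left when each mature sequence was counted once (exact binomial interval 64.77% to 64.78%). miR-21 (uagcuuaucagacugguguugg), which is widely expressed and often rises in injured tissue, came next with 13911397 reads or 5.10%. Of the reads outside miR-122, miR-21 made up 14.5%. The third was the let-7 sequence ugagguaguagguuguauaguu, with 10142987 reads or 3.72%, listed at 5 entries, some of which overlap on scaffolds 10 and 11351. The miR-122 precursor scored under 10, so a score of at least 10 would leave it out. The 10 most abundant mature sequences held 87.2% of mature reads and the first 20 in the whole list held 94.4%.

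The rest of the 20 most abundant sequences followed. The reads beside a name are those of single mature sequences, the most abundant one where 1 value is given, and other sequences can carry the same name. A pair of miR-22a-3p sequences that differ in their last base held 9529100 and 7237252 reads. Their star arms carried 58879 reads each, so reads shared by the pair are not separated. miR-26a-5p held 6306190 reads and was listed at 5 entries. miR-192, enriched in liver and gut, held 4141267 reads or 1.52%. miR-146b, known from the control of inflammation, held 3341038 reads. A pair of miR-100-5p sequences had 3226945 and 1748448 reads. The 2 most abundant miR-148 sequences had 3178975 and 2378945 reads. miR-143 held 2369224 reads, miR-101a 1510404 reads and miR-128-3p 1447633 reads. Let-7 sequences filled 6 of the 20 ranks, and those after the first had between 1458467 and 2801612 reads.

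**Figure D1:**
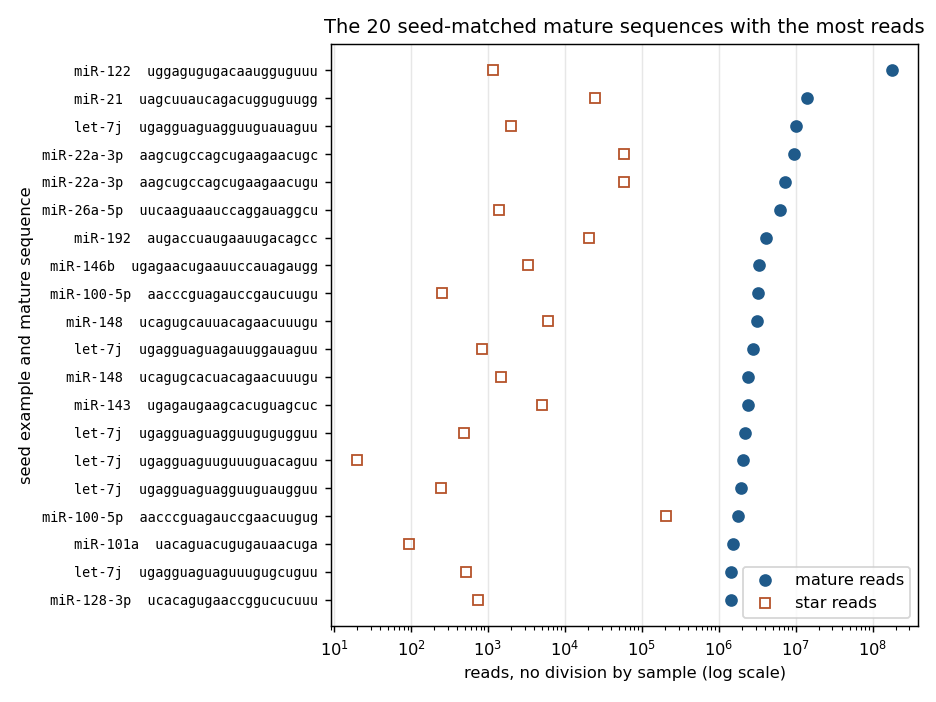
Mature reads (filled circles) and star reads (open squares) of the 20 seed-matched mature sequences with the most reads, with no division by sample, on a log axis; labels give the zebrafish seed example and the eel mature sequence. miR-122 has 176573973 mature reads and miR-21, the next, has 13911397.

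Families of the hepatocyte list held most reads, and lists of other cell types that liver tissue or its blood could bring held far fewer. The hepatocyte list held 66.5% of mature reads over 10 distinct sequences, with entries named for miR-122, miR-192 and miR-194 (miR-194b, 459589 reads). Of those 10 sequences, 8 carry the miR-122 seed and 7 of these have few reads. The leukocyte list held 1.26%, nearly all of it miR-146b, which other cells also express. miR-150 had 4545 reads and miR-155 had 2736. The endothelial list held 0.763%, from miR-126b-3p, whose 2 sequences of 1426038 and 654350 reads differ only in length. The list for mesenchymal or smooth muscle cells held 0.969%, chiefly miR-143 and miR-199-3-3p with 272428 reads. The erythroid list held 0.156%, from 2 miR-451 sequences with 325845 and 98555 reads; miR-451 is abundant in red blood cells. Epithelial or biliary families held 0.0854%, led by miR-200a-3p with 127481 reads and miR-429a with 92317. Families of pancreas or gut held 0.0671%, led by miR-216b with 123605 reads and followed by miR-217 with 46385, miR-375 with 7863 and miR-216a with 5149. The neural or endocrine list held 0.140%, of which miR-7b had 267587 and 94253 reads in sequences of different length, and miR-218b 12096. The muscle list held 0.00608%, with 15475 reads for miR-1 and 278 for miR-499-5p.

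Among families not tied to a cell type, let-7 was the largest, with 14 distinct sequences, 24 entries and 8.88% of mature reads. The stress and hypoxia list held 6.78%, most of it miR-21, and included 944848 reads of miR-181c-5p. The lipid and glucose metabolism list held 2.31%, most of it in miR-148 sequences. The miR-10, miR-99, miR-100 and miR-125 list held 2.23%, with 918850 reads for the most abundant miR-10a-5p sequence and 87112 for that of miR-125a, whose 3 sequences held 140102. miR-30 sequences held 0.711%, led by miR-30a-5p with 1292759 reads and miR-30e-3p with 610352. The miR-181 list held 0.416%, and the Hox cluster list held 0.352%, in which the 3 miR-196a-5p sequences had 393 reads, 272 of them in the most abundant one. The miR-17-92 list held 0.179% over 16 sequences. The lists for miR-23, miR-24 and miR-27 (0.0546%), miR-221 and miR-222 (0.0497%), and miR-15 and miR-16 (0.0426%) were smaller. miR-29a had 807 and 434 reads, or 0.000455% together. This leaves out the unmatched sequence cuagcaccauuugaaaucgguu with 10644 reads, which shares a run of 17 bases with miR-29a but starts 1 base before it. With that sequence, counted after the data were seen, the share was 0.00436%. No entry was named for the early-embryo families among those analysed here. Names stand for seeds, so a family without an entry of its name can be listed under another: miR-92 shares its seed with miR-25, and miR-98 with let-7. A family can also lie among the unmatched sequences, for example if its listed 5′ end is shifted. An unmatched sequence was added for miR-29a only, so the shares of the other lists may be too low. A family without an entry is therefore not shown to be absent. Lists overlap, their shares do not add up, and no spread between eels could be given.

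**Figure D2:**
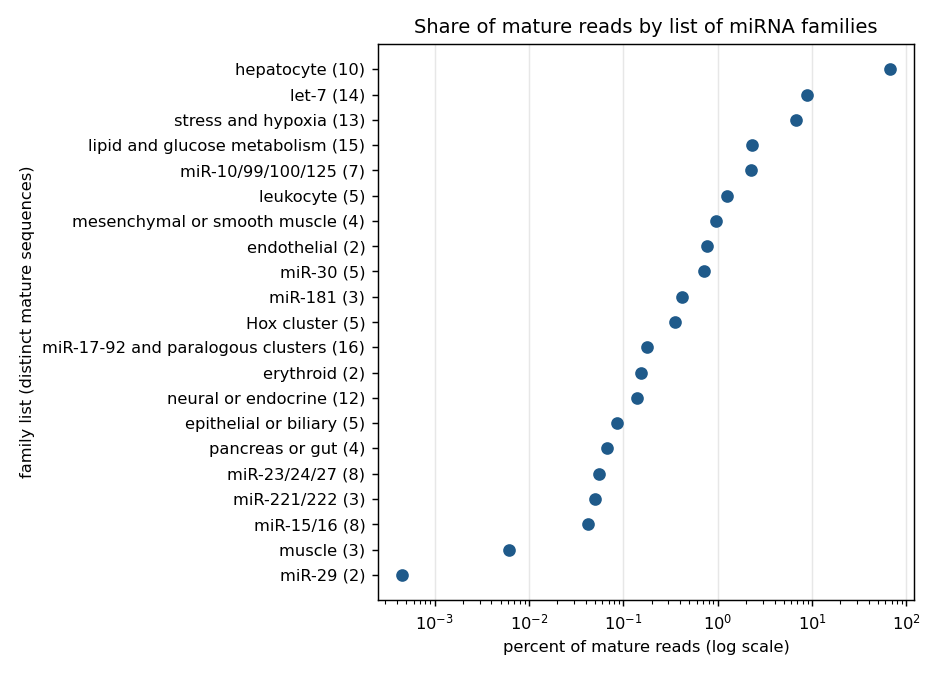
Share of mature reads for each of the 21 family lists with entries, on a log axis, with each mature sequence counted once; the number of distinct mature sequences is in brackets and there are no error bars because the counts are not divided by sample. The hepatocyte list lies at 66.5% and the miR-29 list at 0.000455%, or 0.00436% with an unmatched sequence that shares 17 bases with miR-29a and is not drawn.

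Seed-matched and unmatched predictions were then compared. Unmatched means only that no zebrafish example with the same seed was listed, so known miRNAs can be among these. Seed-matched miRNAs were fewer in sequence and held nearly all reads. Of the 676 distinct mature sequences, 200 shared a seed with a zebrafish miRNA, through 98 seeds, and 476 did not. At a score of at least 10 there were 112 and 180. The 200 held 271731799 mature reads or 99.7%, and the 476 held 857478 or 0.315%. The median was 4346.5 mature reads for a seed-matched sequence and 37.5 for an unmatched one. The unmatched sequence with the highest score and the most reads was uggcaagauguuggcauagcug on scaffold 2789 (35687 to 35746, minus strand), with 358999 mature and 116 star reads. It was followed by uuuugcagaaacguuucagauu with 230207 reads at 2 entries, and by auuccuggaaauacuguucuu on scaffold 199925 with 80310 mature and 7477 star reads. The next were caaugugucugcagugcaac on scaffold 198 with 19655 mature reads and 97 loop reads, and gcgacccacucuugauuucagg on scaffold 1254 with 15634. The same 5 sequences led both rankings.

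No difference between the 2 classes was detected in star reads, which come from the other arm of a cut hairpin. They were seen for 131 of 200 seed-matched sequences (65.5%, interval 58.5% to 72.1%) and for 303 of 476 unmatched ones (63.7%, interval 59.2% to 68.0%; odds ratio 1.08, two-sided Fisher's exact test, adjusted p = 0.661). Each sequence was judged by its entry with the most mature reads, so star reads at its other entries were not counted. For miR-338 that entry had 0 star reads and another had 331. This can miss more star reads in the seed-matched class, with more sequences at several entries. With every entry counted, the odds ratio was 1.11 (Fisher's exact test, unadjusted p = 0.499). The list held no score under 0. Entries without star reads scored up to 3.9 if seed-matched and up to 1 if unmatched. If lower scores were left off the list, this could have removed more unmatched hairpins without star reads. The comparison therefore holds for listed sequences only and cannot tell whether the classes differ beyond the list. The classes did differ in other properties, which were chosen after the list had been seen. Seed-matched sequences more often began with U, the base that Argonaute proteins favour at the 5′ end: 71.5% against 53.2% (odds ratio 2.21, Fisher's exact test, adjusted p = 1.96e-05). They were more often listed at several entries, 38.5% against 5.67% (odds ratio 10.4, Fisher's exact test, adjusted p = 3.16e-24), with an odds ratio of 6.08 among sequences with at least 100 mature reads. They also more often lay in a genomic cluster, 36.5% against 4.20% (odds ratio 13.1, Fisher's exact test, adjusted p = 2.50e-25). A sequence counted as clustered if any of its entries lay in a cluster. Sequences at several entries, more frequent in the seed-matched class, thus had more chances, and the odds ratio makes no allowance for this. Entries include overlapping predictions of 1 locus, so listing at several entries does not count gene copies. A mature sequence on the 5p arm was also more frequent in seed-matched sequences, 59.5% against 45.6% (Fisher's exact test, adjusted p = 0.00142), and so was a score of at least 10, 56.0% against 37.8% (adjusted p = 3.42e-05). A length of 21 to 23 nt was less frequent, 79.5% against 89.1% (Fisher's exact test, adjusted p = 0.00164). The score is not an independent property. High scores followed the total reads, and seed-matched sequences had more reads (medians 4346.5 and 37.5). Of the 72 precursors with over 1000 reads that scored under 10, 67 were seed-matched. The highest score among the 72 was 3.9, and 0.4 for the few unmatched ones. The score may thus depend on the seed match itself. With sequences of 1 seed counted once, star reads were more frequent in the seed-matched class (odds ratio 1.65, Fisher's exact test, unadjusted p = 0.0465). With at least 100 mature reads, star reads were seen for 76.1% of 159 seed-matched and 75.9% of 137 unmatched sequences.

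The most abundant precursor had one of the low scores. miR-122 scored 3.7, although its star arm carried 1153 reads. miR-101a with 1510404 reads scored 3.9, and miR-194b with 459589 reads scored 3.4. By contrast, miR-21 scored 7104894.2. Among the 229 precursors that scored 100 or more, the score was a nearly constant multiple of the total reads, with a median of 0.51 per read and a range from 0.492 to 0.526. No seed-matched entry scored from 4 to under 10, where 55 unmatched entries lay.

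**Figure D3:**
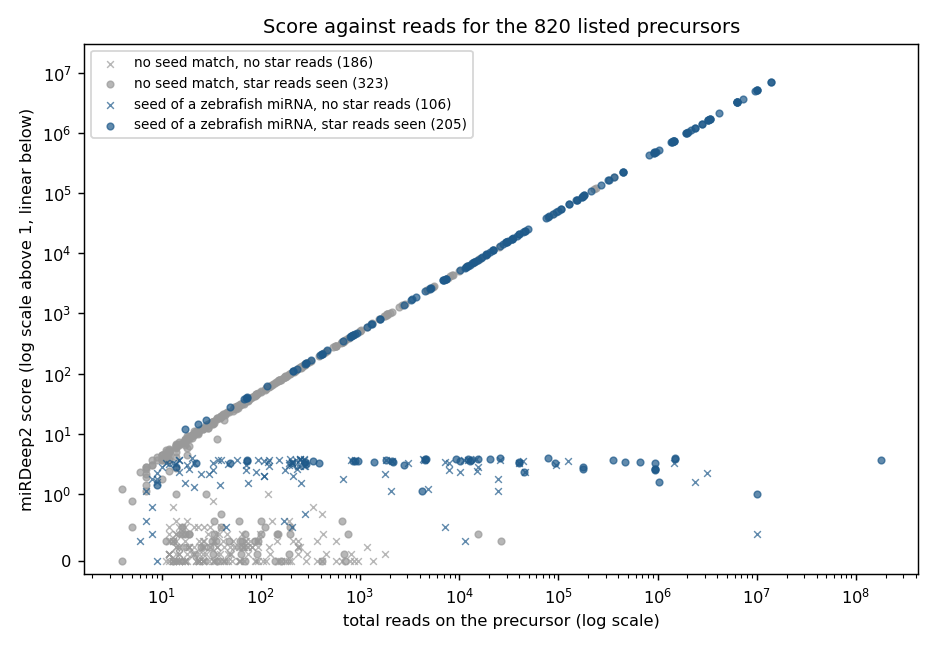
miRDeep2 score (logarithmic above 1 and linear below) against total reads on a log axis for the 820 precursors; blue marks seed-matched and grey unmatched entries, circles those with star reads and crosses those without. Precursors that score 100 or more lie on a line of about 0.51 per read, and a band of seed-matched entries with scores under 4 extends to miR-122 with 176573973 mature reads at the right edge.

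Most precursors gave nearly all reads from 1 arm. Among 792 precursors with at least 10 mature plus star reads, the mature arm held a median of 99.6% (quartiles 91.8% and 100%). The mature sequence lay on the 5p arm in 393 and on the 3p arm in 399. It lay on the 5p arm in 57.3% of the 300 seed-matched precursors (interval 51.5% to 63.0%) and in 44.9% of the 492 unmatched ones (interval 40.5% to 49.4%). Overlapping predictions were not merged here, and 31 pairs in the whole list overlapped on 1 strand. A mature sequence at 1 locus can thus count for both arms, as miR-148 did on scaffold 6210. The intervals treat such predictions and gene copies as independent, which they are not. With each mature sequence counted once, the 5p share was 50.2% of 650. Of the 234 precursors with at least 1000 reads, 38 had a star share above 10%, and 155 had one under 1%. The star share was highest for a miR-29a precursor on scaffold 5821 (38935 to 38993, minus strand), at 62.9% from 434 mature and 736 star reads. An unmatched precursor on scaffold 1303 (acucuuucccuguugcacuacu) came next with 57.5%. The miR-140-5p precursor on scaffold 25873 had 57.0%, with 34079 mature and 45090 star reads, so in these 3 precursors the arm called star had more reads. The other two were unmatched precursors, uccgguuucugaaggcaagacu on scaffold 3242 with 49.9% and acugguuucaggugguggcuuaga on scaffold 14439 with 45.2%. Reads shared with other copies are not separated on either arm.

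The largest genomic clusters belonged to the miR-17-92 group, which is linked to cell growth in vertebrates. The list gave 52 clusters with 124 precursors: 39 of 2, 9 of 3 and 4 of 4 or more. At a score of at least 4 there were 28 clusters. The largest lay on scaffold 269 (96475 to 97311, plus strand), where 6 precursors followed each other in 837 nt. In the direction of transcription they were named miR-20b-5p, miR-18b-5p, miR-19b-3p, miR-20b-5p, miR-19b-3p and miR-25-3p. A second copy on scaffold 54 (256487 to 257286, minus strand) had 5 of them in the same order, without a miR-18b-5p entry. Clusters of 4 lay on scaffold 747 (57393 to 58375, minus strand) and scaffold 861 (76119 to 77493, plus strand), the first of them with an unmatched precursor (acugcgcuaaguguuccuucug, 101 reads). Within each cluster the reads were uneven: on scaffold 269, the miR-25-3p precursor had 180249 mature reads and the miR-18b-5p precursor 288. The first 2 clusters share the miR-25-3p sequence uauugcacuugucccggccugu, and the other two share aauugcacgguauccaucugua with 170891 reads each, so reads of the copies cannot be separated. Of the 52 clusters, 34 were entirely seed-matched, 13 mixed and 5 unmatched.

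**Figure D4:**
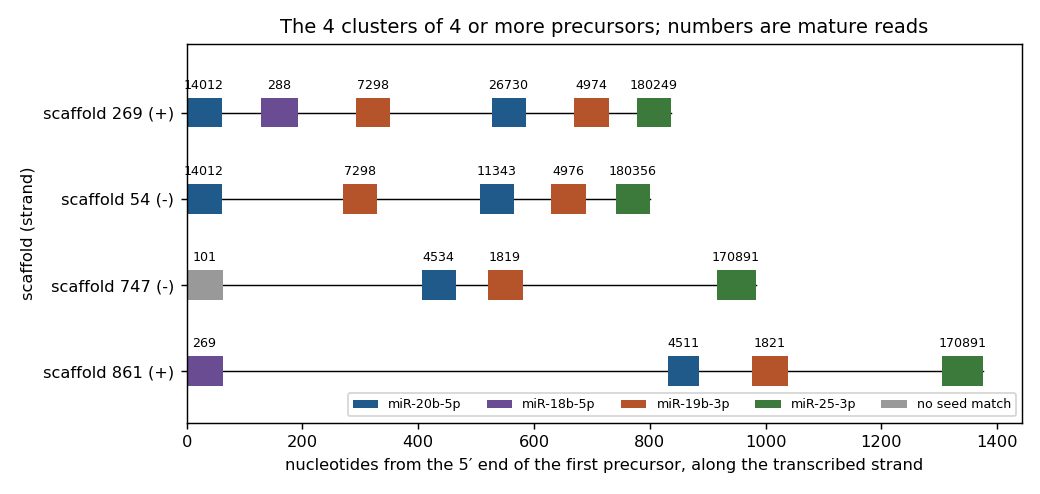
The 4 clusters with 4 or more precursors, drawn to scale from the 5′ end of the first precursor along the transcribed strand; boxes are precursors coloured by seed example, and numbers are mature reads with no division by sample. In all 4 clusters the last precursor carries the seed named miR-25-3p, with between 170891 and 180356 mature reads. Its mature sequence is uauugcacuugucccggccugu on scaffolds 269 and 54 and aauugcacgguauccaucugua on scaffolds 747 and 861. The name gives the seed and does not identify the miRNA.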

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

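Loop reads entered no comparison in the results, and all values in this part were picked out after the list was seen. A count of 0 allows up to 3 reads, and 44 precursors had more loop reads than that, 34 of them seed-matched. In 9 precursors the loop reads also exceeded the star reads. The highest loop count was 402 reads, on the miR-146b precursor of scaffold 692, which had 3321399 mature and 74145 star reads. Next came an unmatched precursor on scaffold 15899 with 195 loop reads and miR-737-5p on scaffold 1507 with 189. Loop reads were 0 in 735 precursors and made up 0.000551% of all reads summed over entries.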

How the results depend on the processing

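The settings of 1 sequence per seed for read shares, of distinct sequences for the arm, of seed-matched clusters and of at least 100 mature reads, and all settings for a 5′ U and for listing at several entries, were chosen after seeing the data. The counts of predictions depended on the score and on how copies were counted. The list shrank from 820 to 406 precursors at a score of at least 4, to 351 at 10, and to 528 with at least 1 star read. Seed-matched sequences went from 200 to 112 at scores of at least 4 and 10, to 311 when each entry counted, and to 98 when each seed counted once. Unmatched ones went from 476 to 235 at a score of at least 4 and to 180 at 10. The share of miR-122 was 64.4% by total reads, 45.5% with reads summed over entries, 72.2% with 1 sequence per seed, and 0% at a score of at least 10, which removes its precursor. The 10 most abundant sequences held 86.8%, 85.3%, 95.2% and 68.9% in the same order. The 5p share rose from 49.6% to 56.0% with at least 1000 reads and to 55.0% at a score of at least 10; the cause was not tested. Clusters fell from 52 to 28 at a score of at least 4, with fewer precursors left. In these alternatives the threshold of 0.05 was set against unadjusted p from Fisher's exact test. The odds ratio for star reads passed it only with each seed counted once (1.65). The main test used an adjusted p, so the 2 are not alike, and the cause was not tested. The odds ratio for listing at several entries went from 10.4 to 6.08 with at least 100 mature reads and to 14.6 with each seed counted once, and stayed past the threshold. That for a 5′ U ran from 2.01 to 2.44, also past it. Clusters numbered 46 at 3 kb and 60 at 50 kb. Leaving out the Rfam alerts moved nothing, and the randfold filter left 0 entries, so neither tests anything. No paired analysis was possible because no column names a sample. No eel could be left out in turn, and the alternatives planned for the comparison of sites were not run, for the same reason.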

Other observations

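The tests on star reads and scores, on the miR-122 seed and on seeds 1 base away were chosen after the results were seen, and so were the miRNAs named here. Only the test on bases 4 to 12 was written before its result. The list also held pairs known from other vertebrates. miR-192 and miR-194b lay next to each other on scaffold 592, with 4141267 and 459589 mature reads. miR-100-5p lay beside a let-7j precursor on scaffolds 1678 and 2237, with 1748448 and 827047 reads on the first and 3226945 and 1938743 on the second. miR-216b, miR-216a and miR-217 lay together on scaffold 2031. miR-182-5p, miR-96-5p and miR-183-5p, known from sensory cells, lay together on scaffold 4014 with 823, 194 and 1303 reads. Both miR-451 precursors had an unmatched neighbour with the sequence cuacaguauagaugauguacu and 9550 reads. In other vertebrates miR-144 sits beside miR-451, but the identity of this neighbour was not tested.

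Among 234 precursors with over 1000 reads, 72 scored under 10, and none of these scored above 3.9. Of the 72, 34 had no star reads, 9 had 1 to 9 and 29 had at least 10. Overlapping predictions count separately here, and some of the 34 overlap a high-scoring entry with the same mature sequence. On scaffold 10, a let-7j entry with 0 star reads and a score of 0.4 overlaps one with 1059 and 5135034.9. No precursor with over 1000 reads and without star reads scored 10 or more (0 of 34), so absent star reads may account for this part. They cannot account for the 29, miR-122 among them. A small share of star reads is also argued against: 50% of the 162 high-scoring precursors had a star share below the median of those 29 (0.547%). What kept the 29 low stays open, and no biological explanation was tested.

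Besides miR-122 itself, 7 entries with 15 to 15143 mature reads carried its seed, and 0 had star reads. Together they held 29245 reads, 0.0166% of the miR-122 count. The 4 with the most reads differed from miR-122 at no more than 2 of the first 18 bases, and may be miR-122 reads with mismatches placed elsewhere. The other 3, with 246, 25 and 15 reads, differed at 4, 7 and 5 of these bases without gaps and at 2, 4 and 3 bases with gaps allowed, and their origin stays open. The star arms left diverged paralogs of the miR-122 gene open too: they were 38.1% to 57.1% identical to that of miR-122, and 4 of the 7 lay below the 5th percentile (48.7%) of 89 pairs from other families with the same seed and 2 to 7 mature differences. The mature sequence lay on the 3p arm on scaffolds 46, 7925, 5009 and 2643, whereas that of miR-122 lay on the 5p arm. Without star reads, the arm rests on the predicted fold alone. On scaffold 10, a let-7j entry with 0 star reads likewise had its mature sequence on the 3p arm. The overlapping entry with 1059 star reads had the same sequence on the 5p arm. The arm therefore cannot decide on paralogs for these 4 entries.

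A further hypothesis was that unmatched sequences include known miRNAs whose listed 5′ end lies 1 base away from the usual one. It was tested only against seeds and seed-matched sequences of this list. A known miRNA listed only in a shifted form could therefore not be found, and the counts do not bear on such miRNAs. For 2 sequences the match went far past the seed, beyond the longest run of 12 bases in 1000 shuffles of all 476. acauucauugcugucggugggu (4736 reads) matched a listed miR-181c-5p sequence over all of its 22 bases, starting 1 base after it, and cuagcaccauuugaaaucgguu (10644 reads) shared 17 bases with miR-29a, starting 1 base before it, and lay beside a miR-29a precursor on scaffolds 1343, 1650 and 5821. Chance is argued against for these 2, which may be members of those families with a shifted listed 5′ end; whether the end is shifted in the eel or by the prediction was not tested. Another 8 held a listed seed 1 base up or down, against a mean of 5.77 and a 95th percentile of 10 in the shuffles (permutation p = 0.222, one-sided), and for all 10 together p was 0.069. For the 8, with a counting SD of 2.83, a shifted end and chance cannot be told apart; this allowance for the SD was made after the counts were seen. A rival idea was that listed seeds are in excess at any position. At bases 4 to 12, 31 held one, against a mean of 26.1 and a 95th percentile of 35 (permutation p = 0.203, one-sided, counting SD 5.57). The rule written before the result took a count at or under that percentile to speak against the idea, and 31 met it. Only the same allowance, made later, leaves the idea open.

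Overlapping predictions on opposite strands formed 26 pairs, and in 7 of them both strands had the same mature sequence. On scaffold 1749, miR-210-5p had 11319 reads and an entry named miR-210-3p on the opposite strand had 40.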
